A study of Mus musculus with 16 samples.

How the data were processed

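Kidney RNA of 4 male mice labelled MFP2-/- was compared with RNA of 1 pool of 5 wild-type males, all aged 15 weeks per the labels, on 16 two-channel cDNA arrays. Each mouse had 4 arrays, in 2 repeats of 2 dye orientations. The deposited values are log2 ratios per probe, 1 column per array, from the authors; their normalisation, background correction, log base and direction are not given in the sources used here. The base was taken as log2 because the most extreme spots, read here as having 1 channel at a floor, had absolute values of 16.1 to 17.0. That reading was not tested. No intensities were used here, so signal over background is unknown.

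The medians of the deposited columns lay between -0.149 and 0.098. Between 127 and 618 of 20355 probes had no value on an array. On each array 12 to 71 spots, 510 in all, shared 1 extreme value; all 292 on arrays with the mutant in Cy5 were positive and all 218 on arrays with the mutant in Cy3 were negative. Values with an absolute size over 10 were treated as missing, a choice made after the data were seen, and their inclusion is among the alternatives. The ratios were taken as already turned to mutant over pool, which stays an inference. Its second basis was that the deviation of a mouse from the mean of all mice, across probes, correlated positively between orientations: the pooled Spearman rho was 0.243 over 161 probes with a repeat SD under 0.1, 0.216 over 1533 probes under 0.15, 0.176 over 5041 under 0.2 and 0.113 over 11674 under 0.3. Mouse 4 gave almost none of this, with a rho of 0.071, 0.049, 0.036 and -0.002 at those limits. These are correlations across probes, which are not independent replicates. Arrays of different mice in the same orientation had a median rho of 0.184 and a minimum of -0.017, and those in opposite orientations a median of -0.101. Arrays of the same mouse in opposite orientations had a median of -0.157. A dye effect also gives negative values between orientations if the ratios run mutant over pool. A median below that of different mice would go against the inferred direction, but the ranges overlap. They were -0.302 to 0.243 over 16 pairs of the same mouse and -0.398 to 0.231 over 48 pairs of different mice. The difference was not tested.

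Probe names came from the platform annotation, which is old, updated by gene identifier through a RefSeq table of assembly GRCm38.p6. Of 20355 probes, 14030 had 1 symbol, 5 had several and 6320 had none; 13994 were updated, and 36 kept the old symbol. Probes with several symbols were left unnamed.

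Each array was centred on its median. A value per mouse was the mean within each orientation and then the mean of both, so that a dye effect cancels if the ratios run mutant over pool. A probe needed both orientations in at least 3 mice, which kept 20187 probes. Probes with the same symbol were averaged and unnamed probes stayed single. The mean over mice was tested against 0 with limma (version 3.58.1, lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05; this leaves out the spread among wild-type animals. Differences between mice were tested with limma's F-test on all 16 arrays with a dye term, and dye with that term, on probes measured in both orientations in all 4 mice, a filter set after the data were seen; the spread there is that between arrays. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 36 lists of at least 3 measured genes, and with an estimated correlation and fry as alternatives. Camera used genes with a value in every mouse tested; list medians without a mouse are over those genes, and other list medians are over all measured members.

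The tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule was the 12 largest mean ratios in each direction among genes past the threshold with plain symbols and the same sign in every mouse measured, or, if none passed, the 12 with the smallest p, given as values only. It did not say whether those 12 were to be taken in each direction; they were, a reading made after the data were seen. It also named Hsd17b4, the 4 members with the smallest p of each list past its threshold, and the 8 genes with the smallest p between mice. Alternatives covered centring, scaling by median absolute deviation, probes on their own, filters on missing values, all arrays with the mouse as a random block (duplicateCorrelation, statmod 1.5.0), medians, single dye orientations, single repeats, a robust prior, an unmoderated test, a minimum change of 0.2 (treat) and leaving out each mouse. Alternatives chosen after seeing the data kept the floor spots, read the values as Cy5 over Cy3, or centred arrays on the third of probes with the smallest repeat SD.

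The scripts were tested on simulated data with the spread of each gene kept. The noise was normal and independent between genes, and held no error of the pool. The shares below therefore do not show what was missed in the real data. For mutant over pool, over 16140 rows with 200 changed, 55.2% of genes changed by 0.5 on the log2 scale were called, 88.1% of those changed by 1 and 93.9% of those changed by 2, with 6 unchanged rows called. For differences between mice over 15856 rows, with mouse 1 alone shifted, 7.5%, 64.2% and 90.9% were called at those sizes. For dye it was 34.3%, 82.1% and 95.5%. No value column was left unmapped. One mouse carries 1 identifier in its titles and another in its source name, and was treated as 1 mouse.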

Results

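Kidney RNA of 4 male mice labelled MFP2-/-, aged 15 weeks, was hybridised against RNA of 1 pool of 5 wild-type males on two-channel cDNA arrays. MFP2 is the peroxisomal multifunctional protein 2, encoded by Hsd17b4, which acts in the beta-oxidation of very long chain and branched fatty acids and of bile acid intermediates. Each mouse was measured on 4 arrays, 2 in each dye orientation, which gave 16 arrays with 19737 to 20228 values each. The arrays of 1 mouse share their RNA and were averaged, so n is 4 mice. The pool is 1 control sample, and the spread among wild-type animals was not measured. The number of arrays limits the precision of each value.

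The first comparison addressed which transcripts differ between kidneys of mice labelled MFP2-/- and the wild-type pool, starting with the targeted gene. Hsd17b4 had 2 probes, and they disagreed. The log2 ratio of probe 4590 was -1.69 in mouse 1, -1.50 in mouse 2, -0.10 in mouse 3 and -0.34 in mouse 4, with a mean of -0.91 ± 0.81 (SD, n = 4). Probe 1446 had 0.02 in mouse 1, 0.83 in mouse 2, 0.34 in mouse 3 and 0.52 in mouse 4, with a mean of 0.43 ± 0.34 (SD, n = 4). The direction, mutant over pool, is likely rather than stated: the labels list the mutant as the first channel on every array. Spots that shared 1 extreme value per array were also positive with the mutant in Cy5 and negative with the mutant in Cy3. That would happen if ratios were already turned one way and the same dye were at a floor, which was not tested. The log2 base was also inferred from the values. If the sign were opposite on every array, each higher value in the text would be a lower one. If the values were instead Cy5 over Cy3 on every array, limma called 12 rows, all lower, and camera called 1 list.

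On the arrays themselves, probe 4590 lay below -1 on all 8 arrays of mice 1 and 2, between -0.23 and 0.07 on the arrays of mouse 3, and between -1.15 and 0.47 on those of mouse 4. Averaged over both probes, Hsd17b4 had a log2 ratio of -0.24 ± 0.45 (SD, n = 4), with a limma adjusted p of 0.655 after Benjamini-Hochberg adjustment. The part of the transcript that each probe covers is not given in the sources used here, so neither probe checks the genotype on its own. The labels are therefore used as given, and the animals are called mice labelled MFP2-/-.

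**Figure D1:**
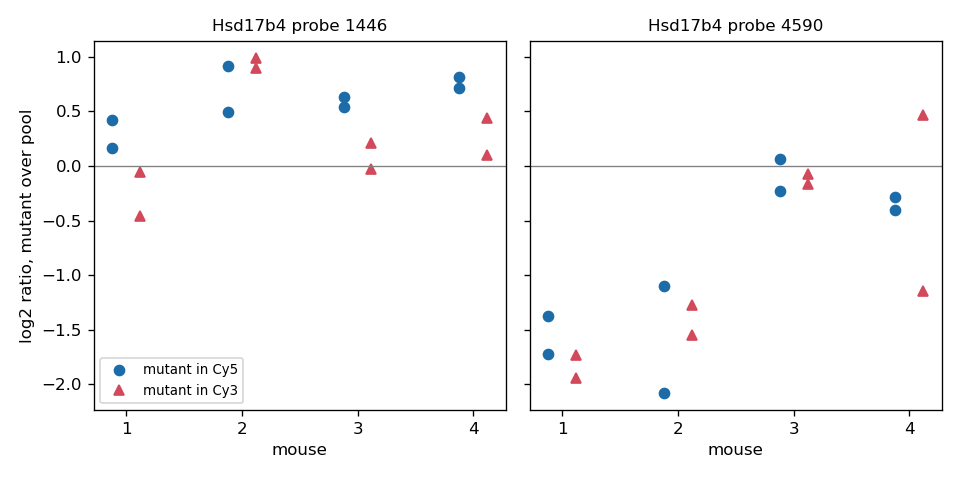
Log2 ratio of mutant over pool (vertical axis) of both Hsd17b4 probes on each of the 16 arrays, by mouse (horizontal axis); circles are arrays with the mutant in Cy5 and triangles arrays with the mutant in Cy3. Probe 4590 lay below -1 on all 8 arrays of mice 1 and 2, while probe 1446 lay below 0 on 3 of the 16 arrays.

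Across the array, the genes with the smallest p on the higher side included Gstm5, Cyp2d9 and Hsd3b4. Gstm5, a glutathione S-transferase, had a log2 ratio of 0.60 ± 0.10 (SD, n = 4), and Cyp2d9, a cytochrome P450 known for sex-dependent expression, had 0.53 ± 0.07. Hsd3b4, a 3-beta-hydroxysteroid dehydrogenase family member of the mouse kidney, had 0.42 ± 0.04, and Inmt, an indolethylamine methyltransferase, had 0.54 ± 0.16. Dbp, a transcription factor driven by the circadian clock, had 0.43 ± 0.09, and Hmgn2, a nucleosome-binding protein, had 0.39 ± 0.09. On the lower side, Dnaja1, a co-chaperone of Hsp70, had -0.78 ± 0.18, and Hspa1a, the inducible Hsp70 chaperone, had -1.26 ± 0.40. Gigyf1 had -0.32 ± 0.05, and Bag3, another Hsp70 partner, had -0.39 ± 0.16.

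None of these genes passed the test. Of 16140 rows tested (9846 genes and 6294 unnamed probes), limma with Benjamini-Hochberg adjustment called 0 at 0.05, and the smallest adjusted p was 0.327. At an unadjusted p under 0.05 there were 1459 rows, 941 higher and 518 lower, where chance gives about 807. The unmoderated one-sample test and the test against a minimum change each called 0 as well. A fit to all 16 arrays with the mouse as a random block called 258 rows, 209 higher and 49 lower; it lets arrays of 1 mouse count almost as separate samples, since its estimated correlation within mice was -0.011.

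Was, a regulator of actin in blood cells, had 1.10 ± 0.43 (SD, n = 4), and Sra1 had 0.44 ± 0.13. Zfp644 had 0.68 ± 0.18, with 0.29 on arrays with the mutant in Cy5 and 1.07 on those with the mutant in Cy3. Gstt3 had 0.67 ± 0.05 in the 3 mice measured, with 0.06 and 0.83 in the same order. Those orientation values also draw on mouse 2, which the mean leaves out. For Dlk1, a secreted Notch-related protein, the mean was 0.81 ± 0.32, but it was -0.60 on arrays with the mutant in Cy5 and 2.21 on those with the mutant in Cy3. Zfp609, with a mean of 0.43 ± 0.09, likewise had -0.07 and 0.92. Celf2, an RNA-binding protein, had a mean of -0.36 ± 0.11 but -0.77 and 0.06 in the 2 orientations, and Unc119, measured in 3 mice, had -0.36 ± 0.06 but -1.19 and 0.42. The orientation values of Unc119 also draw on mouse 2, which its mean leaves out. Both probes of Gstm5 were positive (0.74 and 0.47) and both of Bag3 negative (-0.46 and -0.33), whereas those of Gigyf1 had 0.06 and -0.71 and those of Dlk1 0.00 and 1.61. The remaining lower genes were Plk2 (-1.04 ± 0.60), Epha6 (-0.38 ± 0.17), Hc, the complement component C5 (-0.30 ± 0.09), Rcan1 (-0.30 ± 0.09), Tmem209 (-0.25 ± 0.04) and, in 3 mice, Nxpe4 (-0.62 ± 0.29). Nxpe4 had -1.19 with the mutant in Cy5 and -0.18 with it in Cy3, values that also draw on mouse 2, which its mean leaves out. Plk2 had -1.39 and -0.70. The repeat SD, between arrays of 1 mouse in 1 orientation, was 1.36 for Gstt3, 1.43 for Unc119, 1.65 for Nxpe4 and 1.99 for Plk2. It was 0.16 for Hsd3b4 and for Hmgn2. A small SD between mice, in genes picked by their p, is therefore not a measure of array precision.

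**Figure D2:**
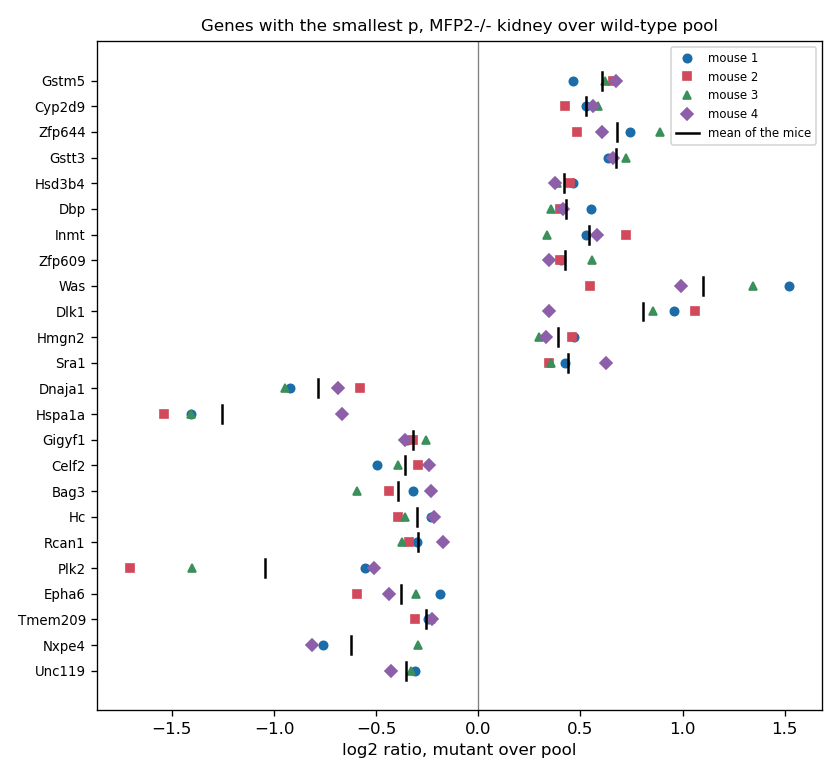
Log2 ratio of mutant over pool (horizontal axis) of the 12 genes with the smallest p in each direction (vertical axis); symbols are the 4 mice and the vertical line is their mean. Every mouse measured lies on the same side of 0 for each gene, from Hspa1a at a mean of -1.26 to Was at 1.10, and none of the 24 genes passed the adjusted threshold.

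Gene lists written before the data were examined asked whether functional groups were displaced together. Of 36 lists, 11 passed limma's camera test with its preset correlation of 0.01 and Benjamini-Hochberg adjustment, 10 higher and 1 lower. With an estimated correlation none of the 11 calls held, and the smallest camera adjusted p was 0.57. Among the 11 lists the estimated correlation ran from -0.11 for distal tubule to 0.56 for loop of Henle. It was 0.46 for ribosomal proteins and 0.52 for oxidative phosphorylation, against the preset 0.01. The rotation test fry called 0 lists, with a smallest adjusted p of 0.189 and no comparison against other genes. Over all genes tested, 0 members of any list passed limma's threshold. Mouse 2 had the highest median of the 4 mice in 8 of the 10 higher lists. On arrays with the mutant in Cy5 alone 9 calls held. On arrays with the mutant in Cy3 alone, 3 calls held (ribosomal proteins, mitochondrial fatty acid oxidation and heat shock). The lists that lost the call there kept medians above 0 over the genes in the test. These ran from 0.08 for oxidative phosphorylation to 0.27 for loop of Henle. With values read as Cy5 over Cy3 the 1 call was oxidative phosphorylation.

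Ribosomal protein genes were called higher as a group at the preset correlation alone (camera adjusted p = 8.29e-14, and 0.57 with an estimated correlation). Their median log2 ratio was 0.19 over 61 measured members, 56 of them positive. The medians were 0.07, 0.43, 0.06 and 0.23 in mice 1 to 4, and the list median was 0.11 without mouse 2. Rps16 had 0.32 ± 0.10 (SD, n = 4), Rplp0 had 0.28 ± 0.08 and Rpl23 had 0.32 ± 0.19; Rpl22 had 0.30 ± 0.06, with -0.24 on arrays with the mutant in Cy5. Adjusted over the list alone, 0 members passed, and 22 had an unadjusted p under 0.05 in limma.

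Mitochondrial lists lay higher too. The 69 oxidative phosphorylation genes had a median of 0.14, 62 of them positive (camera adjusted p = 1.84e-08; adjusted p = 0.57 with an estimated correlation), with medians of -0.03, 0.40, 0.07 and 0.16 in the 4 mice. Without mouse 2 the median was 0.06, and without mouse 1 it was 0.22. Among them, Cox5b, a cytochrome c oxidase subunit, had 0.22 ± 0.13 (SD, n = 4), Atp5b, a subunit of ATP synthase, had 0.30 ± 0.22, and the complex I subunits Ndufv1 and Ndufc1 had 0.26 ± 0.18 and 0.39 ± 0.28. The 24 mitochondrial fatty acid oxidation genes had a median of 0.16, 21 positive (camera adjusted p = 1.39e-05; adjusted p = 0.57 with an estimated correlation), and 0.10 without mouse 2. Slc22a5, the carnitine transporter, was the 1 member past limma's threshold adjusted over the list alone, at 0.29 ± 0.03 and positive in 4 of 4 mice. Etfdh, Acaa2 and Hadha, enzymes of mitochondrial beta-oxidation and its electron transfer, had 0.34 ± 0.17, 0.29 ± 0.19 and 0.23 ± 0.15. Adjusted over its list alone, the oxidative phosphorylation list had 0 members past the threshold.

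The peroxisomal oxidation list, which holds the partners of the targeted enzyme, had a median of 0.10 over 33 measured genes, 26 of them positive (camera adjusted p = 0.000299; adjusted p = 0.57 with an estimated correlation). Slc27a2, a very long chain acyl-CoA synthetase, had 0.41 ± 0.23 (SD, n = 4), Acaa1a, a peroxisomal thiolase, had 0.34 ± 0.23, Abcd3, a peroxisomal transporter, had 0.23 ± 0.11 and Eci3 had 0.37 ± 0.36. No member passed limma's threshold, over all genes or adjusted over the list alone (0 of 33), and 7 had an unadjusted p under 0.05. Without mouse 2 the list median was 0.06. The separate list of 23 PPAR alpha targets outside the peroxisome had a median of 0.01, 13 members positive and 10 negative, with a camera adjusted p of 0.407. The 16 peroxins and membrane proteins had a median of 0.06 (camera adjusted p = 0.246).

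Antioxidant and glutathione genes had a median of 0.13 over 37 members, 26 positive (camera adjusted p = 0.000299; adjusted p = 0.57 with an estimated correlation). Gstm5, as above, and Gsta2, an alpha-class glutathione S-transferase with 0.66 ± 0.27 (SD, n = 4), were the 2 members past limma's threshold adjusted over the list alone. Sod2, the mitochondrial superoxide dismutase, had 0.40 ± 0.20, and Gstm1 had 0.31 ± 0.21. Without mouse 2 the list median was 0.07.

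The unfolded protein response and heat shock list was the 1 list that was lower, with a median of -0.11 over 23 genes, 17 of them negative (camera adjusted p = 0.000299; adjusted p = 0.57 with an estimated correlation). Hspa1a and Dnaja1 were the 2 members past limma's threshold adjusted over the list alone, both negative in 4 of 4 mice. Hsp90aa1, the inducible cytosolic Hsp90, had -0.45 ± 0.29 (SD, n = 4), and Herpud1, a protein of endoplasmic reticulum quality control, had -0.32 ± 0.20. Other members of the unfolded protein response were mixed. Atf4 had -0.16 ± 0.09 and Hspa5 -0.30 ± 0.46, but Xbp1 had -0.02 ± 0.22, Pdia4 0.02 ± 0.11 and Dnajc3 0.02 ± 0.27. Heat shock and unfolded protein response members were not tested apart. The list median was -0.30 in mouse 1 and -0.31 in mouse 3, but 0.02 in mouse 2 and 0.04 in mouse 4. Over the mice that remained it was -0.07 without mouse 1, -0.22 without mouse 2 and -0.07 without mouse 3.

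Of the nephron lists, camera called those of proximal tubule, loop of Henle and distal tubule, and not those of intercalated cells (camera adjusted p = 0.108), principal cells (0.255) or podocytes (0.874). The intercalated list nevertheless had a median of 0.14 over 10 genes, against 0.10 for proximal and for distal tubule and 0.14 for loop of Henle. Whether the shift differs between nephron lists was not tested. Proximal tubule markers (25 genes, 20 positive) had a median of 0.10 (camera adjusted p = 0.00165; adjusted p = 0.57 with an estimated correlation), with Napsa at 0.31 ± 0.11 (SD, n = 4) and Cubn, the endocytic receptor cubilin, at 0.25 ± 0.10. The call was lost without mouse 2 (median 0.06, camera adjusted p = 0.106) and without mouse 4 (median 0.09, camera adjusted p = 0.0515). Gluconeogenesis and ammonia genesis genes (17, 13 positive) had 0.15 (camera adjusted p = 0.00391; adjusted p = 0.57 with an estimated correlation), with Ldhb at 0.42 ± 0.25, Fbp1 at 0.31 ± 0.21, Glud1 at 0.30 ± 0.22 and Slc37a4 at 0.24 ± 0.14. Neither list had a member past limma's threshold adjusted over the list alone (0 and 0). Loop of Henle markers (10 genes, 7 positive) had 0.14, and Slc12a1, the sodium-potassium-chloride cotransporter, was the 1 member past the threshold adjusted over the list alone, at 0.56 ± 0.24; Wfdc15b and Ppp1r1a had 0.40 ± 0.30 and 0.36 ± 0.27 (camera adjusted p = 0.0361; adjusted p = 0.57 with an estimated correlation). The call was lost without mouse 3 (median 0.05, camera adjusted p = 0.0583) and without mouse 4 (median 0.13, camera adjusted p = 0.177). Over the 8 genes in the test the median was 0.17. The call was also lost with medians of arrays (median 0.16, camera adjusted p = 0.0747), with every probe in 2 or more mice (0.17, 0.0569), with the mutant in Cy5 alone (0.20, 0.0554) and on repeat 1 (0.14, 0.111).

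Distal and connecting tubule markers (8 genes, 7 positive) had 0.10, with S100g, the calcium-binding protein calbindin-D9k, as the 1 member past limma's threshold adjusted over the list alone, at 0.65 ± 0.39 (SD, n = 4) (camera adjusted p = 0.0361; adjusted p = 0.57 with an estimated correlation). Wnk4 had 0.18 ± 0.13 and Slc8a1 0.13 ± 0.22, while Pvalb had 0.11 ± 0.13 with -0.17 on arrays with the mutant in Cy5. This call was lost without mouse 1, 2 or 4, with medians of 0.09, 0.11 and 0.07 and camera adjusted p of 0.0691, 0.109 and 0.0687. It was also lost on probes with a value on all arrays (median 0.10, camera adjusted p = 0.0553), with the mutant in Cy5 alone (0.11, 0.109), on repeat 1 (0.08, 0.149) and with floor spots kept (0.10, 0.107). Proteasome genes (32, 29 positive) had a median of 0.10 (camera adjusted p = 0.000897; adjusted p = 0.581 with an estimated correlation), with Psmb1 at 0.28 ± 0.18, Psma4 at 0.24 ± 0.16, Psmb3 at 0.19 ± 0.07 and Psma6 at 0.13 ± 0.10, and 0 members adjusted over the list alone. Without mouse 2 the proteasome call was lost (median 0.03, camera adjusted p = 0.434). The other 25 lists did not pass, with camera adjusted p from 0.0874 to 0.907.

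**Figure D3:**
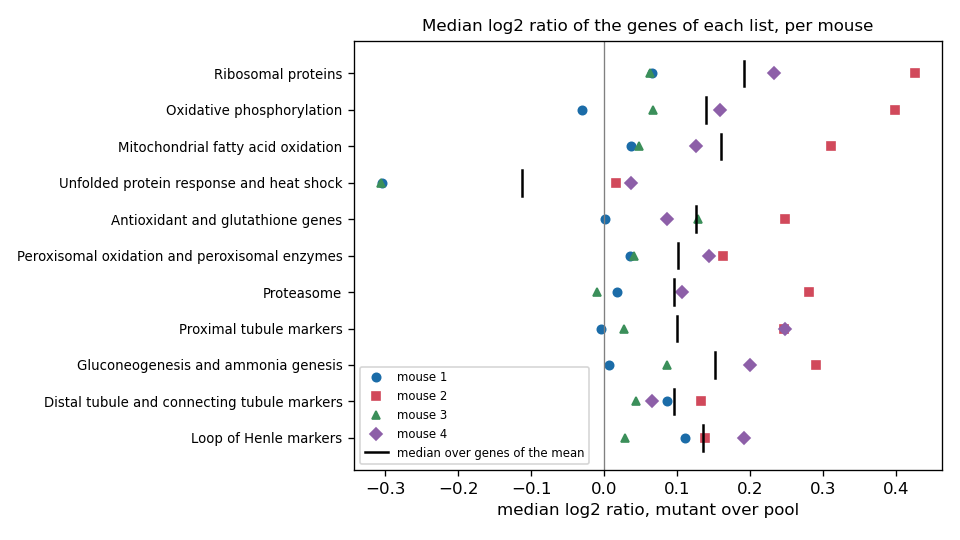
Median log2 ratio of mutant over pool (horizontal axis) over the genes of each of the 11 lists past the camera threshold with its preset correlation (vertical axis), for each mouse (symbols); the vertical line is the median over genes of the mean of the mice. The ribosomal protein median ranges from 0.06 in mouse 3 to 0.43 in mouse 2. The median of the unfolded protein response and heat shock list lies below 0 in mice 1 and 3. It lies just above 0 in mice 2 and 4.

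The second comparison asked whether the 4 mice differed from one another by more than arrays of 1 mouse did. Ndrg1, a stress-responsive gene, had log2 ratios of -0.88, 0.44, 0.29 and 0.04 in mice 1 to 4 (SE 0.09 from the spread between arrays), and Ugt3a2, a glycosyltransferase, had -0.45, 0.71, 0.20 and 0.98. Slco1a6, an organic anion transporter, had -1.05, -0.04, -0.52 and 0.30. Star, which carries cholesterol into mitochondria for steroid synthesis, had 0.20, -0.87, 0.72 and -0.04. Creld2, induced by endoplasmic reticulum stress, had -0.71, 0.42, -0.59 and 0.17.

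Limma's F-test with Benjamini-Hochberg adjustment called 30 of 15856 rows, and 1776 had an unadjusted p under 0.05, where chance gives about 793. Cd82, Gabarapl1 and Mtor completed the 8 named genes with adjusted p of 0.00916 each; Mtor, a growth-control kinase, had -0.84 in mouse 1 and 0.29 to 0.46 in the others. Of the 30 rows, 23 were lowest in mouse 1 and 20 highest in mouse 2, with ratios read as mutant over pool. With values read as Cy5 over Cy3 the test called 2 rows, 0 of them among the 30, and the 8 named genes had adjusted p of 0.954 or more. Those 2 were the unnamed probes 8201 and 2773, named after their values were seen. The count was 4 without the dye term, 16 after scaling the arrays and 51 on probes with a value on all arrays. It was 1 on arrays with the mutant in Cy5 and 12 on those with the mutant in Cy3. Without mouse 1 the count was 5, without mouse 2 it was 12, without mouse 3 it was 7 and without mouse 4 it was 13.

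The third comparison was between dye orientations. It measures a dye effect if the ratios run mutant over pool; if they are Cy5 over Cy3, the same difference is one between mutant and pool. Gimap6 differed by -5.91 on the log2 scale between arrays with the mutant in Cy5 and in Cy3, Ftcd by -4.14, Mrpl53 by -3.90 and Dbndd1 by -4.61. Limma called 1332 of 15856 rows for orientation after Benjamini-Hochberg adjustment, 585 higher and 747 lower with the mutant in Cy5, which is 8.4% of the rows. Read as Cy5 over Cy3, the dye term called 260 rows, and the test over the 4 mouse means called 12 rows between mutant and pool, all lower. The count for orientation was 46 without mouse 1, 2701 without mouse 2, 44 without mouse 3 and 75 without mouse 4. Without centring each array the count was 2740, of which 2079 were higher and 661 lower.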

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

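All explanations of the Hsd17b4 probes, and the dye test of the list shifts, were tested after the result was seen; the test on matched genes, the test without mouse 2 and the counts over other splits were fixed before their results were seen. Hspa1a stood out for 1 mouse far from the others: its log2 ratio was -0.67 in mouse 4 against -1.41, -1.54 and -1.41 in mice 1 to 3. It was 1 of 73 values screened in this way, and chance picks about 1 in 20.

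The shift of 10 lists upwards together (ribosomal, mitochondrial, peroxisomal, proteasome and nephron genes) is open. A dye bias cannot be told apart: 10 of the 10 lists had a median above 0 in both orientations, which speaks against it only if the ratios run mutant over pool, and with values read as Cy5 over Cy3 1 of them still passed. A shift shared by every gene with a small difference between repeats is argued against. Over 10000 random draws of genes matched on that difference, the median was -0.002 and the highest 0.03. The lists' pooled median of 0.14 over 313 genes lay at percentile 100 of these draws. As the lists were called higher in the same data, that percentile by itself decides little. Whether mouse 2 carries the shift cannot be told apart from a shift in all mice, since 7 of the 10 lists still passed without it (all but the proteasome, proximal tubule and distal tubule lists), fewer than the 8 set beforehand for a shift in all mice and not under the 3 set for mouse 2 alone. Without it the median over the genes in the test fell from 0.14 to 0.06 for oxidative phosphorylation, which still passed, from 0.10 to 0.03 for the proteasome and from 0.10 to 0.06 for proximal tubule. It rose from 0.10 to 0.11 for distal tubule and from 0.17 to 0.18 for loop of Henle. Yet mouse 2 had the highest distal tubule median of the 4 mice, at 0.13. Camera does not test the median, so this rise does not decide whether the lost distal call comes from mouse 2. On the arrays of mouse 2, 539 to 618 probes had no value, against at most 416 on any other array. Floor spots numbered 55 to 71 there, against at most 35 elsewhere. Whether this bears on the lists was not tested. Between mice, limma's F-test gave 35 of 69 oxidative phosphorylation genes an unadjusted p under 0.05. For ribosomal proteins it was 25 of 61, and for mitochondrial fatty acid oxidation 4 of 23. A bias tied to brightness itself remains possible, as no intensities were used here, and a biological effect of genotype stays untested against wild-type spread.

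The signs of the mice could be turned in 8 distinct patterns, too few for a share under 0.05. The real pattern gave 11 lists and the highest other pattern also gave 11, in 2 of the 8 patterns. For genes the count past the threshold was 0 in 8 of 8 patterns, which decides nothing. At an unadjusted p under 0.05 the real pattern had 1459 rows, the other 7 had 343 to 960, and the one that matched on lists had 601. All mice were set against the same pool, so a deviation of that pool would also raise the count of the real pattern. The pattern that matched on lists set mice 1 and 3 against mice 2 and 4, so the count of lists does not separate a shift shared by the mice from a contrast between those pairs.

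The 2 Hsd17b4 probes disagreed, and both differed between mice. Spread between arrays of 1 mouse is argued against for the lower one, because the between-mouse p in limma, unadjusted and with ratios read as mutant over pool, was 5.7e-05 for probe 4590; it was 0.00417 for probe 1446. A mislabelled mouse cannot be told apart from other causes: 2 of the 4 mice lay below -1, where 1 wrong label would leave 3, and 2 wrong labels may be possible. Which exons the probes cover, and whether probe 1446 reads another transcript, was not tested. A difference in genotype or in the remaining transcript also stays open.

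For the differences between mice, with ratios read as mutant over pool, 1 of 100 regroupings of the arrays, the real one, gave 30 rows, and the highest of the others gave 2. This sets separate RNA samples against repeat hybridisations alone, so it does not exclude chance differences between animals. For dye orientation, 1 of 100 regroupings, the real one, gave 1332 rows, and the highest of the others gave 1.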

How the results depend on the processing

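The readings of the values as Cy5 over Cy3, with the floor spots kept, and centred on quiet probes were chosen after seeing the data. The count of 0 genes was also 0 under centring, scaling, single probes, both filters, medians, single repeats, the robust prior, the unmoderated test, treat, each mouse left out, floor spots kept and centring on quiet probes. It was 258 with the mouse as a random block and 221 with a dye term added, where the estimated correlation of 0.035 lets arrays of 1 mouse count almost as separate samples. It was 3 on arrays with the mutant in Cy5, 1 on those with the mutant in Cy3 and 12, all lower, with values read as Cy5 over Cy3; the cause was not tested. Without 1 mouse it ranged from 0 to 0, and Hsd17b4 from -0.36 to -0.04.

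The averaged Hsd17b4 ratio of -0.24 was reversed on probe 1446 alone, at 0.43, and with values read as Cy5 over Cy3, at 0.09. The 11 lists became 0 with an estimated correlation and 0 with fry, 3 on arrays with the mutant in Cy3 and 1 with values read as Cy5 over Cy3, and ranged from 8 to 11 without 1 mouse; the cause was not tested. The 30 rows between mice became 4 without the dye term, 16 after scaling, 1 on arrays with the mutant in Cy5, 12 on those with the mutant in Cy3 (fewer arrays) and 51 on probes with a value on all arrays, 2 with values read as Cy5 over Cy3, and ranged from 5 to 13 without 1 mouse. The 1332 rows for dye orientation became 2740 without centring and 260 with values read as Cy5 over Cy3, and ranged from 44 to 2701 without 1 mouse.

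Of 1310 values of named genes under alternatives, 34 changed sign and 69 passed the threshold. Most of the 69 came from the fits with the mouse as a random block. The only other settings with calls had 3, 1 and 12 rows in all. On arrays with the mutant in Cy5 these had the opposite sign: Zfp609 -0.068, Dlk1 -0.60, Rpl22 -0.24 and Pvalb -0.17; on those with the mutant in Cy3, Celf2 0.06 and Unc119 0.42; on repeat 1, Dlk1 -0.009 and Pvalb -0.072. With values read as Cy5 over Cy3, so did Zfp644 -0.39, Gstt3 -0.15, Zfp609 -0.49, Dlk1 -1.41, Sra1 -0.16, Dnaja1 0.14, Hspa1a 0.088, Gigyf1 0.017, Bag3 0.11, Rcan1 0.10, Epha6 0.20, Rpl22 -0.54, Ndufc1 -0.29, Cox5b -0.009, Ndufv1 -0.037, Etfdh -0.26, Hadha -0.064, Hsp90aa1 0.15, Herpud1 0.17, Napsa -0.032, Ldhb -0.16, Glud1 -0.019, Wnk4 -0.009, Pvalb -0.28, Slc8a1 -0.074 and Wfdc15b -0.035; the medians of the mitochondrial fatty acid oxidation list (-0.042) of the heat shock list (0.088) and of the distal tubule list (-0.013) turned as well. Of 198 list values, 54 no longer passed with the camera direction kept, and 2 more changed direction and did not pass. Of 95 values of genes between mice, 47 no longer passed. Signal over background, which limits dim spots, is unknown.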

Other observations

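The test on genes near Hsd17b4 was fixed before its result was seen and the test on adrenal markers after. Several lists that did not pass the camera test held members past limma's threshold adjusted over the list alone. In the clock list (14 genes, camera adjusted p = 0.157) these were Dbp at 0.43 ± 0.09 (SD, n = 4), Tef, a related clock output factor, at 0.32 ± 0.07, and Cry1, a core repressor, at -0.27 ± 0.13, each with the same sign in 4 of 4 mice, although Cry1 had -0.60 on arrays with the mutant in Cy5 and 0.05 on those with the mutant in Cy3; Nfil3, which opposes Dbp, had -0.20 ± 0.13 and did not pass. In the androgen-responsive list (8 genes, camera adjusted p = 0.246) they were Hsd3b4 at 0.42 ± 0.04 and Odc1, the rate-limiting enzyme of polyamine synthesis, at -0.29 ± 0.13. Nr1h4, the bile acid receptor FXR, had 0.30 ± 0.09 in the bile acid list (12 genes, camera adjusted p = 0.246), and Aqp2, the vasopressin-regulated water channel, had 0.46 ± 0.25 among principal cell markers (9 genes, camera adjusted p = 0.255). None passed over all genes tested, where limma called 0 and 1459 rows had an unadjusted p under 0.05.

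Rbm3, an RNA-binding protein induced by cold and chosen here after its values were seen, had 0.54 ± 0.32 (SD, n = 4), and Cirbp, a related cold-induced gene, had 0.08 ± 0.14. Lists of other cell types and states did not pass the camera test. Median log2 ratios were -0.04 for extracellular matrix, 0.14 for intercalated cells, 0.05 for lysosome, 0.05 for cholesterol synthesis and 0.09 for tubular injury. They were -0.06 for red blood cells, 0.05 for liver, 0.07 for adrenal, 0.04 for fatty acid synthesis, 0.02 for cell cycle, 0.03 for endothelium and -0.01 for class II antigen presentation. For macrophages the median was -0.03, for smooth muscle and juxtaglomerular cells 0.04, for lymphocytes -0.02, for interferon-induced genes 0.02, for podocytes 0.00, for immediate early genes 0.01 and for adipocytes -0.02. Their camera adjusted p lay between 0.0874 and 0.907. The median was positive but the mean and camera direction negative for liver. The median was negative but the mean and camera direction positive for adipocytes and for principal cells, which had a median of -0.008. For endothelium the mean alone was negative, and for macrophages, lymphocytes and podocytes the mean alone was positive.

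Star and Chgb, genes of adrenal cortex and medulla, both differed between mice with ratios read as mutant over pool, with mouse 3 highest and mouse 2 lowest. Adrenal tissue in some samples is a candidate explanation, tested on the other 7 markers of a list written beforehand. Their median difference, mouse 3 minus mouse 2, was 0.29, at percentile 95.87 of 10000 matched random lists and short of the percentile set for it, and 4 of the 7 were higher in mouse 3. Chga differed by 0.69, Hsd3b1 by 0.63, Cyp21a1 by 0.47 and Cyp11a1 by 0.29, but Fdx1 by -0.21, Cyp17a1 by -0.10 and Nr5a1 by -0.07, and the explanation stays open.

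Strain DNA flanking the targeted gene could leave neighbouring genes displaced. Over the 40 measured genes nearest to Hsd17b4, 20 on each side in the gene order of assembly GRCm38.p6, the mean absolute log2 ratio was 0.13 against a median of 0.10 over windows of that size, at percentile 93.7, which does not reach the 95 set beforehand. In limma 3 of the 40 had an unadjusted p under 0.05, against 1459 of all 16140 rows. That 0 of the 40 passed the adjusted threshold decides nothing, since 0 of all rows passed. The question stays open.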
